A study of Homo sapiens with 10 samples.

How the data were processed

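H3K27ac was measured by ChIP-seq in MCF-7 cells, whose chromatin was fixed with formaldehyde, after 24 h in medium with serine, without serine, or without serine plus GTA. The series holds 10 samples: 2 H3K27ac libraries for each of 3 media, 1 input for each medium and 1 IgG sample. The 6 H3K27ac libraries come with peak lists and were used. The IgG sample and the 3 inputs come with no peak list and were left out, so no background level is given.

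Per the submitters' processing notes, reads were handled with Bowtie2 2.3.5.1, Picard 2.24.2, deepTools 3.3.2, bedtools and MACS2 on build hg38. The notes name no version for bedtools and MACS2. Peaks were called by the authors in each library by itself. The peak-calling threshold and the control used are not given in the sources used here, and the smallest deposited -log10 q was 1.30. The deposited lists hold, per peak, its start, its end and the summit position in bp (positions), the authors' score (a whole number from 10 times -log10 q, unit score), the authors' fold enrichment over local background (a ratio), and the authors' -log10 p and -log10 q. These scores, ratios and -log10 values are the authors' own for each peak and served here to rank and filter peaks within a library. Beyond that, only the medians of the -log10 q and of the fold enrichment were compared between libraries. The lists hold no read counts, so the depth of the libraries is unknown and no counting interval can be given for a single peak.

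Peaks of all libraries were merged where they overlapped by at least 1 bp into 45113 regions, and a region counted as marked in a library with any peak in it. Similarity was the Jaccard index of covered base pairs. A region was lost without serine when it was marked in both serine-fed libraries and in neither serine-free library without GTA, and gained in the opposite case, with the same rule for the other comparisons. The other splits of the same 4 libraries into pairs gave the counts that mixed media reach. Shares carry exact Clopper-Pearson intervals at 95%, which cover counting error only, and odds ratios come from Fisher's exact test, two-sided. Means of libraries were compared by exact permutation tests, two-sided. Lost and gained regions were counted in bins of 1 Mb and set against 1000 shuffles. In the 12 bins with most lost regions the length covered in kept regions and their rank within a library were compared between media and set against the other bins with at least 5 kept regions, after the data were seen.

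The gene table (RefSeq, GRCh38.p14, the coordinates of hg38) gives no strand, so start sites are unknown: windows of 25 kb around either gene end replaced windows around start sites, and "near a gene end" (within 1 kb of either end of a protein-coding gene) replaced promoters. Exons and introns cannot be given. For each of 19974 protein-coding genes on chromosomes 1 to 22 and X the covered length was summed per library. The 14983 genes with a mean of at least 500 bp were tested as log2 of the length plus 200 bp in limma 3.58.1 (R 4.3.3) with a trended prior, 3 residual degrees of freedom and 4.45 prior ones, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Neighbouring genes share windows, so calls were also counted as separate loci.

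A total of 12 gene lists fixed from textbook knowledge (312 entries) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 12 lists of a comparison. The lists are estrogen receptor targets, luminal identity, serine, glycine and one-carbon metabolism, the ATF4 amino acid response, acetyl-CoA and histone acetylation, sterol and lipid synthesis, cell cycle, p53 targets, NRF2 oxidative stress, basal and mesenchymal identity, blood cell identity and housekeeping genes. For serine removal each list's median was also placed among 10000 random lists matched on covered length in 20 bins. Named genes were, per comparison, the 10 largest positive and 10 largest negative changes among called genes whose groups did not overlap, the 4 members of each list with the smallest p for serine removal, and GREB1, TFF1, PGR, MYB, XBP1, ESR1, FOXA1, GATA3, PHGDH, PSAT1, ASNS, ACSS2 and ACLY. Named regions were the 10 of each kind with the highest mean rank by the authors' -log10 q. Genes of the loci with many lost regions (GFRA1 and others) were chosen after their values were seen. Comparisons, tests, lists, the naming rule and most alternatives were set before the data were examined.

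The alternatives were peaks with -log10 q of at least 5, the same number of strongest peaks per library, at least 50% of a region covered, merging over gaps of up to 500 bp, chromosomes 1 to 22 and X, libraries centred on their medians, pseudocounts of 50 and 1000 bp, no filter, windows of 10 and 50 kb, replicate number as a block, robust moderation and each library left out in turn. Added after the data were seen were the whole gene span, centring within each chromosome and an adjustment for the number of genes within 500 kb (lowess, span 0.3).

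The steps were tested on simulated data. Merging and covered length matched a base-by-base count in 200 simulated sets (4200 checks, 0 mismatches). In 10 simulated data sets with 200 changed genes limma found 43.0% of changes of 0.5 and 90.7% of changes of 1 on the log2 scale, and 6.70% of its calls were false. Comparisons that share libraries were set against 100 simulations without any difference. The share of the serine change returned with GTA was taken from covariances across genes that have no library in common, with a jackknife interval over 23 chromosomes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for all other steps.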

Results

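MCF-7 cells, an estrogen receptor-positive breast cancer line, were kept for 24 h in medium with serine, in medium without serine, or in medium without serine plus GTA. H3K27ac, a histone mark of active promoters and enhancers that needs acetyl-CoA to be made, was mapped by ChIP-seq in 2 libraries per medium. The comparisons ask whether serine removal lowers the mark, above all at genes that answer to estrogen, and whether GTA brings it back. GTA is read as glyceryl triacetate, a source of acetate, from general knowledge of such work, since the labels give the letters alone.

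The marked part of the genome covered about the same length with and without serine but was divided differently. Peaks were called in each library by itself, and no read counts or inputs were used. The covered length therefore cannot show whether the overall level of the mark changed. Serine-fed libraries held 34532 ± 1100 peaks (mean ± SD) over 52.4 ± 0.609 Mb, and serine-free libraries held 31768.5 ± 549 peaks over 52.95 ± 0.817 Mb. The median peak width was 1050.0 ± 43.8 bp with serine and 1296.5 ± 2.12 bp without it. Libraries with GTA held 32879 ± 991 peaks over 56.3 ± 1.06 Mb, with a median width of 1307.5 ± 36.1 bp. In exact permutation tests, two-sided, with 2 libraries against 2 there are 6 splits and no p under 0.333. The peak numbers gave exact p = 0.333 in each of the 3 comparisons, and the covered length without serine against with serine gave p = 0.667. The serine-fed libraries were also the least enriched, with a median -log10 q per peak of 10.4 and 12.3 against 15.6 to 17.3 in the serine-free libraries and a median fold enrichment of 6.93 and 7.595 against 8.38 to 8.93. These medians also depend on the depth, which is unknown, and on the number of weak peaks called, so they are no direct measure of library quality. The difference follows serine and lies under every comparison with the serine-fed libraries below. The difference in peak number depended on weak peaks: among peaks with the authors' -log10 q of at least 5 the serine-free mean minus the serine-fed mean was 269, against -2763.5 over all peaks.

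The marked territory followed serine more than it followed GTA. The serine-fed and serine-free peak sets shared a mean Jaccard index of 0.659, and the serine-fed and GTA sets 0.664. The serine-free sets with and without GTA shared 0.747, close to the mean of 0.757 between replicates (0.732 to 0.772). Replicates resembled each other more than libraries of different media did, by 0.0672 on average. That was the highest of the 15 ways to pair 6 libraries (next highest 0.0491; exact p = 0.0667, the smallest these pairings allow). Nothing in the labels says that replicates are separate cultures, so the p-values of permutation tests and limma rest on the spread between these libraries, which may be technical. Fisher's exact test counts regions, and camera at the preset correlation sets the genes of a list against other genes. Neither measures a spread between cultures.

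**Figure D1:**
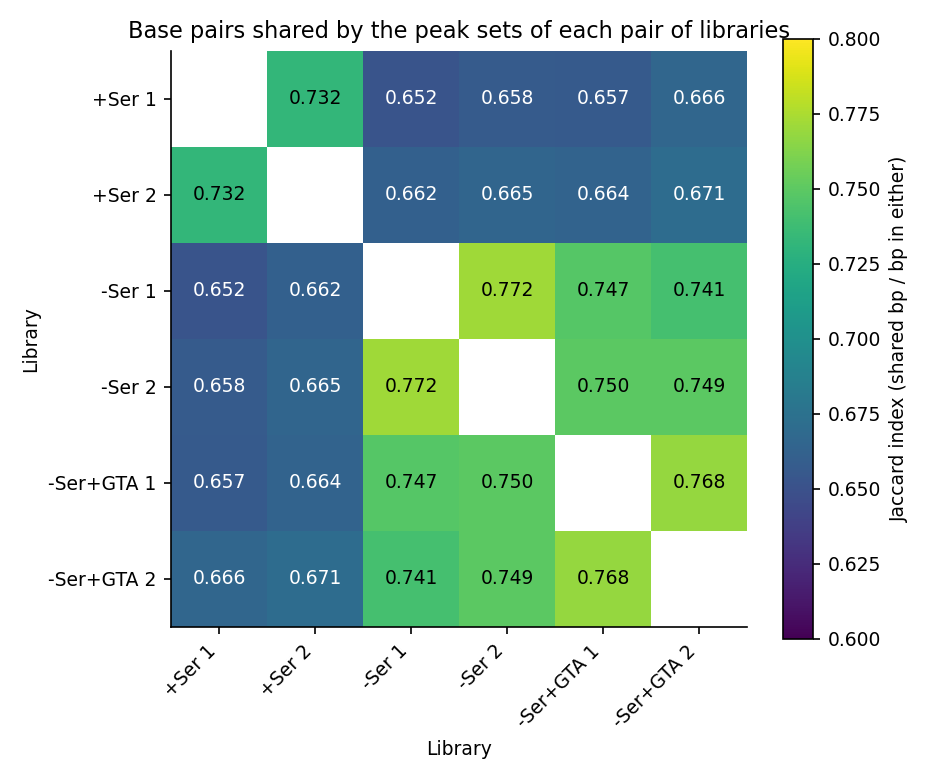
Jaccard index (shared base pairs over base pairs in either library) for each pair of the 6 H3K27ac libraries. Pairs of a serine-fed and a serine-free library without GTA average 0.659 and pairs of serine-free libraries with and without GTA average 0.747.

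Many regions marked with serine lacked the mark without it, and a similar number were marked without serine only, most of them away from gene ends. Of 45113 regions with a peak in any library, 20240 (44.9%) were marked in all 6 libraries. Without serine 2427 regions were lost, that is, marked in both serine-fed libraries and in neither serine-free library without GTA, and 2095 were gained. These were 9.84% of the 24668 regions of the serine-fed libraries and 8.58% of the 24431 regions of the serine-free ones. Splits of the same 4 libraries that mix the media gave 233 to 406 regions. A stricter peak threshold (-log10 q of at least 5) lowered the lost regions to 1360 and left 1939 gained. With the same number of strongest peaks per library 1863 were lost and 2402 gained, so which kind was more frequent depended on the peaks used. Without serine-fed replicate 1 or 2 the lost regions numbered 6091 and 7268, and without serine-free replicate 1 or 2 the gained regions numbered 4486 and 4100, since 1 library then stands for its medium.

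Among the strongest lost regions were sites inside DLGAP1, TEX14, AFF3 and THSD7B and over an end of PANX2, at 62.4 to 66.3 mean percentile of their libraries by the authors' -log10 q. The strongest lost region of all, at percentile 71.0, lay 49.7 kb from OR13H1. Strong gained regions lay within XPC, a DNA damage recognition gene (percentile 74.7), within PREP and JAK1, and 123 kb from VEGFA, the vascular growth factor gene (percentile 68.1). Each of the 10 strongest gained regions was also marked in both GTA libraries. Most regions that changed were weak: the median percentile was 25.8 for lost and 26.4 for gained regions, against 69.1 for kept regions in the serine-fed libraries, and none of the lost regions stood above the 75th percentile (the authors' scores rank peaks within a library only). Within 1 kb of an end of a protein-coding gene lay 10.0% of the lost regions (95% interval 8.85 to 11.3, counting error only), 7.02% of the gained regions (5.96 to 8.20) and 48.0% of the regions kept in both media. The odds of lying near a gene end were 0.121 (0.105 to 0.138) for lost against kept regions and 0.0818 (0.0690 to 0.0970) for gained against kept regions. Kept regions were also wider, with a median of 2438 bp against 824 bp for lost and 1032.5 bp for gained regions. Regions were not matched on width or rank, so these odds may reflect wide and strong peaks rather than serine. Both p-values of Fisher's exact test, two-sided, were below the smallest number the software represents. Lost regions lay near gene ends more often than gained ones (odds ratio 1.48, 1.19 to 1.83, exact p = 0.000363), but regions are not replicates, and no test here rests on cultures.

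**Figure D2:**
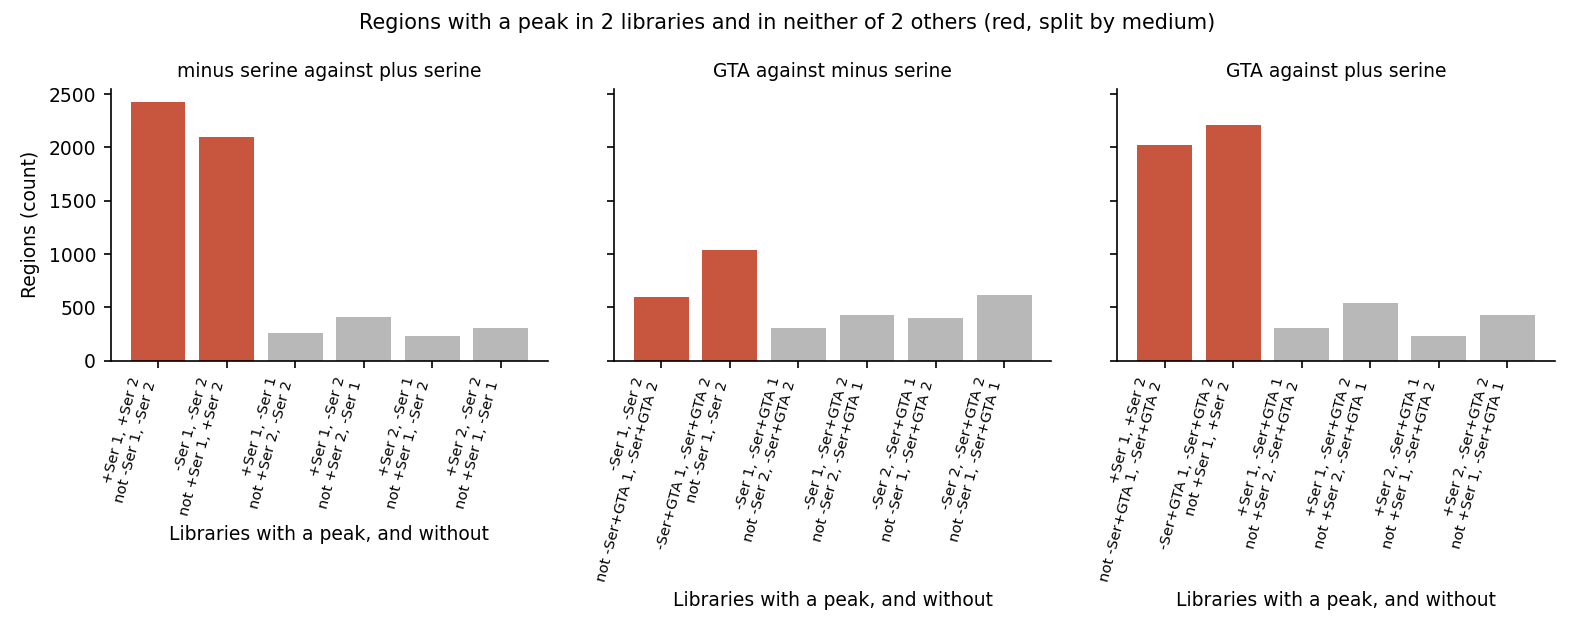
Number of regions marked in both libraries of a pair and in neither library of another pair, for the 3 comparisons; red bars follow the media and grey bars mix them. Splits by serine hold 2427 and 2095 regions against 233 to 406 in mixed splits, and splits by GTA alone hold 597 and 1036 against 305 to 620.

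Lost regions gathered at single loci, of which those named here were chosen after their values were seen. Of the regions marked in both serine-fed libraries between 116 and 117 Mb of chromosome 10, around GFRA1, a receptor for a glial growth factor, 18 of 30 were lost and none of the 18 was marked in both GTA libraries. GFRA1 itself fell from 25.3 ± 4.80 to 12.05 ± 0.541 kb (log2 -1.05, adjusted p = 0.00279) and stood at 12.3 ± 0.693 kb with GTA. Around PREX1, which activates a small GTPase, 16 of 28 regions were lost between 48 and 49 Mb of chromosome 20, and around NCAM2, a cell adhesion gene, 16 of 33 between 21 and 22 Mb of chromosome 21. The bins of CUX1 on chromosome 7 (18 of 47) and GSE1 on chromosome 16 (18 of 63) stood equally high. In 1000 shuffles of the lost regions over all regions of the serine-fed libraries no 1 Mb bin held more than 16, so the GFRA1, CUX1 and GSE1 bins stood above the shuffles and the PREX1 and NCAM2 bins did not exceed them, while the highest gained bin, 8, was reached in 837 shuffles. Among peaks with -log10 q of at least 5, the PREX1 bin lost 12 of 22 regions and alone stood above the shuffles, which held at most 11. The NCAM2 bin lost 10 of 22, and the GFRA1, CUX1 and GSE1 bins lost 6, 7 and 8.

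**Figure D3:**
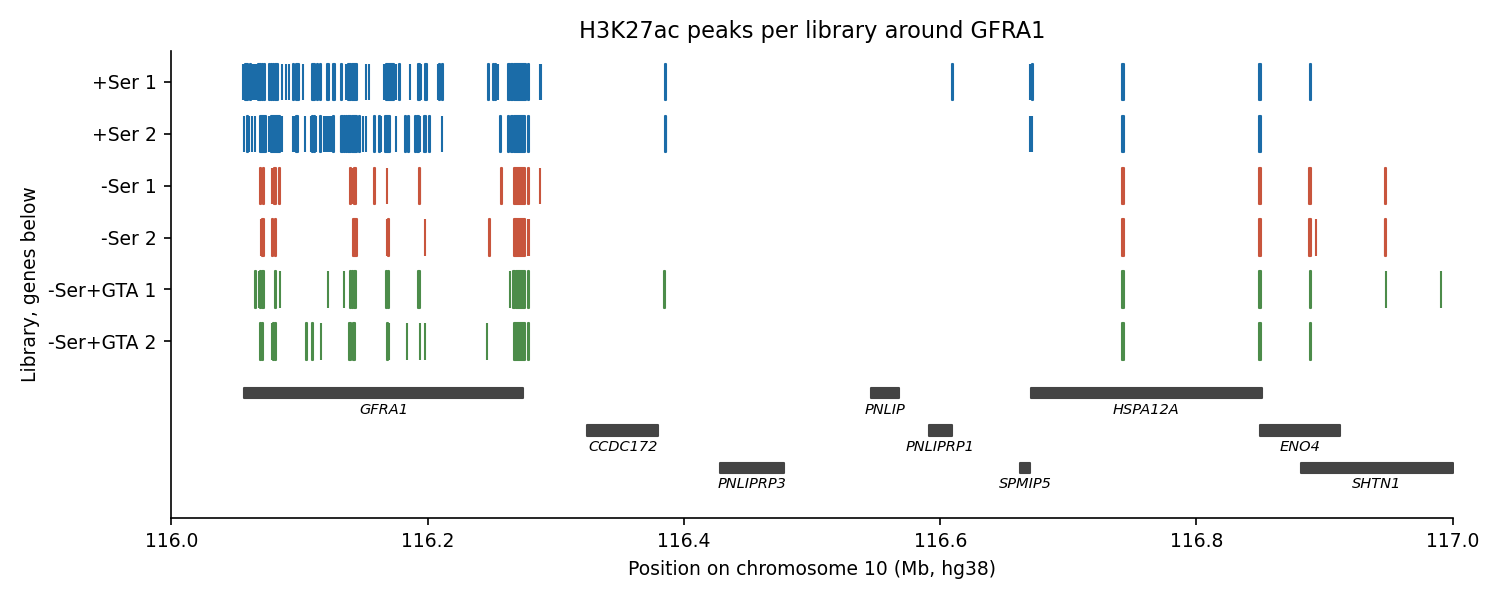
H3K27ac peaks (coloured bars, hg38 position in Mb) in the 6 libraries between 116 and 117 Mb of chromosome 10, with gene spans below. Of 30 regions marked in both serine-fed libraries 18 were marked in neither serine-free library without GTA.

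Most regions lost without serine also lacked the mark with GTA. Of the 2427 lost regions, 1585 (65.3%, 63.4 to 67.2) were marked in neither GTA library, 497 (20.5%) in 1, and 345 (14.2%, 12.8 to 15.7) in both. Of the gained regions 1264 of 2095 (60.3%, 58.2 to 62.4) were marked in both GTA libraries. Over 84 other assignments of the 6 libraries to pairs the same share ran from 3.28% to 66.7% with a median of 18.7%. Some of these assignments keep the libraries of a medium together, so the range can hold the serine split itself. It therefore does not decide whether either share is unusual. The 345 regions absent from the serine-free libraries without GTA alone lay at CAMK2N2, an inhibitor of a calcium-dependent kinase, at CYP4F11, a fatty acid hydroxylase, and inside CAMTA1, ADAP1 and TBC1D10B, among others. Of these regions 21.2% (17.0 to 25.9) lay near a gene end. With the roles of the serine-free media exchanged, 129 of 2027 regions (6.36%, 5.34 to 7.52) that GTA libraries lacked were marked in the serine-free libraries without GTA. Among the 15 pairs of libraries, the serine-free pair without GTA ranked second by regions absent from it alone, after the serine-fed pair, and the GTA pair ranked 4 with 129. The share of 14.2% moved to between 6.77% without serine-fed replicate 2 and 26.6% without GTA replicate 1. It was 7.57% without serine-fed replicate 1, 19.6% and 23.7% without serine-free replicate 1 or 2, and 22.2% without GTA replicate 2. These moves follow in part from the rule, since 1 library then stands for its medium.

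Part of the estrogen receptor targets lost coverage without serine. Of 39 measured targets 11 fell, 3 rose and 25 did not pass the test, and adjusted over the list alone 15 fell and 4 rose. With libraries centred on their medians 18 fell and 3 rose. Covered length is the length under peaks within 25 kb of either gene end. GREB1, an estrogen-induced growth regulator, fell from 22.8 ± 1.39 to 15.3 ± 0.0346 kb (2 libraries each, log2 -0.57, adjusted p = 0.00262). SLC39A6, a zinc transporter gene, fell from 33.5 ± 0.482 to 24.3 ± 0.193 kb (log2 -0.46, adjusted p = 0.00206), and ELOVL2, a fatty acid elongase, from 5.22 ± 0.224 to 2.04 ± 0.650 kb (log2 -1.31, adjusted p = 0.00511). RARA, a retinoic acid receptor (log2 -0.25, adjusted p = 0.00686), PGR, the progesterone receptor (log2 -0.45, adjusted p = 0.0258), and XBP1, a factor of the unfolded protein response (log2 -0.23, adjusted p = 0.0162), also fell. At the stricter peak threshold the calls of PGR (log2 -0.27, adjusted p = 0.141) and XBP1 (log2 -0.15, adjusted p = 0.104) ended. The PGR call also ended with equal peak numbers (log2 -0.27, adjusted p = 0.126) and the XBP1 call with centring within chromosomes (log2 -0.16, adjusted p = 0.220). Both calls ended as well without either serine-fed or either serine-free replicate (log2 -0.44 to -0.46 for PGR, -0.21 to -0.26 for XBP1). Over the alternatives the adjusted p ranged from 0.00347 to 0.141 for PGR and from 0.00327 to 0.220 for XBP1. TFF1, a secreted trefoil peptide, stood at 9.20 ± 0.131 and 8.11 ± 0.372 kb (log2 -0.18, adjusted p = 0.153) and MYB at 8.77 ± 0.169 and 7.75 ± 0.511 kb (log2 -0.18, adjusted p = 0.197). TFF1 passed as lower with libraries centred on their medians (log2 -0.27, adjusted p = 0.0447) and MYB with centring within chromosomes, added after the data were seen (log2 -0.38, adjusted p = 0.0231), in ranges of 0.0269 to 0.454 and 0.0231 to 0.734. The list median was -0.19, below all but 0.01% of 10000 random lists matched on covered length. In camera, which compares a list with all other genes, the targets were lower (adjusted p = 0.00113; adjusted p = 0.256 with an estimated correlation). The estimated correlation of this list was -0.0045, below the preset 0.01. The higher p of that form of camera (unadjusted 0.0221 against 0.000197) therefore does not come from a higher correlation between the genes of the list.

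Genes of luminal identity moved the same way in part. Of 24 measured members 7 fell, 1 rose and 16 did not pass, and adjusted over the list alone 8 fell and 4 rose. ESR1, the estrogen receptor gene itself, fell from 38.5 ± 0.515 to 28.6 ± 0.225 kb (log2 -0.43, adjusted p = 0.00173). SPDEF, an epithelial transcription factor, fell from 19.0 ± 2.23 to 9.60 ± 0.291 kb (log2 -0.97, adjusted p = 0.00173), with KRT8, a luminal keratin (log2 -0.27, adjusted p = 0.00365), and MLPH (log2 -0.30, adjusted p = 0.00371). FOXA1, the pioneer factor of the estrogen receptor, stood at 19.8 ± 0.259 and 19.8 ± 0.345 kb (log2 0.00, and -0.08 with libraries centred on their medians), and GATA3 at 40.8 ± 0.361 and 39.0 ± 0.119 kb (log2 -0.07, adjusted p = 0.217). GATA3 passed as lower with libraries centred on their medians (log2 -0.15, adjusted p = 0.0228), in a range of 0.00474 to 0.592. The list was lower in camera (adjusted p = 0.0288; adjusted p = 0.256 with an estimated correlation), but its median of -0.04 stood at percentile 84.8 of matched random lists. After centring on library medians 10 luminal genes fell and none rose, with a median of -0.13. The camera call ended with 50 kb windows (adjusted p = 0.0670), with no filter (0.105), without serine-fed replicate 2 (0.103) and without serine-free replicate 2 (0.0932), in a range over the alternatives of 0.00284 to 0.105.

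Many targets of the amino acid response gained coverage without serine. Of 31 genes of the ATF4 response 13 rose, none fell and 18 did not pass, and adjusted over the list alone 17 rose and 1 fell. VEGFA, also near a strong gained region, rose from 6.10 ± 1.02 to 12.4 ± 0.436 kb (log2 1.01, adjusted p = 0.00274). TRIB3, a stress pseudokinase, rose from 21.9 ± 1.19 to 30.1 ± 1.02 kb (log2 0.46, adjusted p = 0.00315), SESN2, an inhibitor of growth signalling, from 5.60 ± 0.262 to 8.38 ± 0.125 kb (log2 0.56, adjusted p = 0.00594), and CEBPG, a partner of ATF4, from 2.03 ± 0.0962 to 3.49 ± 0.0099 kb (log2 0.73, adjusted p = 0.00858). ASNS, asparagine synthetase, rose from 1.18 ± 0.0615 to 1.91 ± 0.0651 kb (log2 0.61, adjusted p = 0.0189), but did not pass with 50 kb windows (log2 0.23, adjusted p = 0.122, range 0.0181 to 0.122). The ASNS call also ended without serine-fed replicate 1 (log2 0.57) and without serine-free replicate 1 (0.64) or 2 (0.58). The list was higher in camera (adjusted p = 0.00113; adjusted p = 0.258 with an estimated correlation), with a median of 0.33.

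Part of the p53 targets also gained coverage. Of 21 measured targets 8 rose and none fell, both over all genes and adjusted over the list alone. TP53INP1, a p53-induced nuclear protein, rose from 2.28 ± 0.124 to 4.62 ± 0.344 kb (log2 0.96, adjusted p = 0.00195), CDKN1A, the cell cycle inhibitor p21, from 5.79 ± 0.436 to 10.0 ± 0.173 kb (log2 0.78, adjusted p = 0.00229), BBC3, a pro-apoptotic gene, from 12.4 ± 0.0771 to 19.0 ± 0.682 kb (log2 0.61, adjusted p = 0.00296), and GDF15, a stress cytokine, from 13.0 ± 0.306 to 18.5 ± 0.740 kb (log2 0.51, adjusted p = 0.00315). The list was higher in camera (adjusted p = 0.00113; adjusted p = 0.256 with an estimated correlation), with a median of 0.26. With libraries centred on their medians 7 rose and none fell, with a median of 0.17. SESN2 is a member of this list and of the amino acid list.

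In the serine, glycine and one-carbon pathway 6 of 25 measured genes rose and none fell, and adjusted over the list alone 7 rose. SHMT2, the mitochondrial enzyme that splits serine, rose from 2.77 ± 0.0841 to 5.30 ± 0.191 kb (log2 0.89, adjusted p = 0.00183), MTRR, which reactivates methionine synthase, from 2.32 ± 0.194 to 5.85 ± 0.0361 kb (log2 1.27, adjusted p = 0.00111), and PHGDH, the first enzyme of serine synthesis, from 1.02 ± 0.235 to 1.76 ± 0.0792 kb (log2 0.70, adjusted p = 0.0290). The PHGDH call ended with 50 kb windows (log2 0.12, adjusted p = 0.548; range 0.0261 to 0.548), with the density adjustment, with centring within chromosomes and without serine-fed replicate 1 or either serine-free replicate. MTHFD1L rose as well (log2 0.58, adjusted p = 0.0170), and SLC1A4, a serine transporter gene, was listed at 0 kb in both serine-fed libraries and at 0.794 ± 0.564 kb without serine (adjusted p = 0.0287). PSAT1 was too little covered to be tested. As a whole the list did not pass camera (adjusted p = 0.288; median 0.12). After centring on library medians 5 genes rose and 1 fell (median 0.04), and with centring within chromosomes 3 rose and 2 fell (median -0.03).

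**Figure D4:**
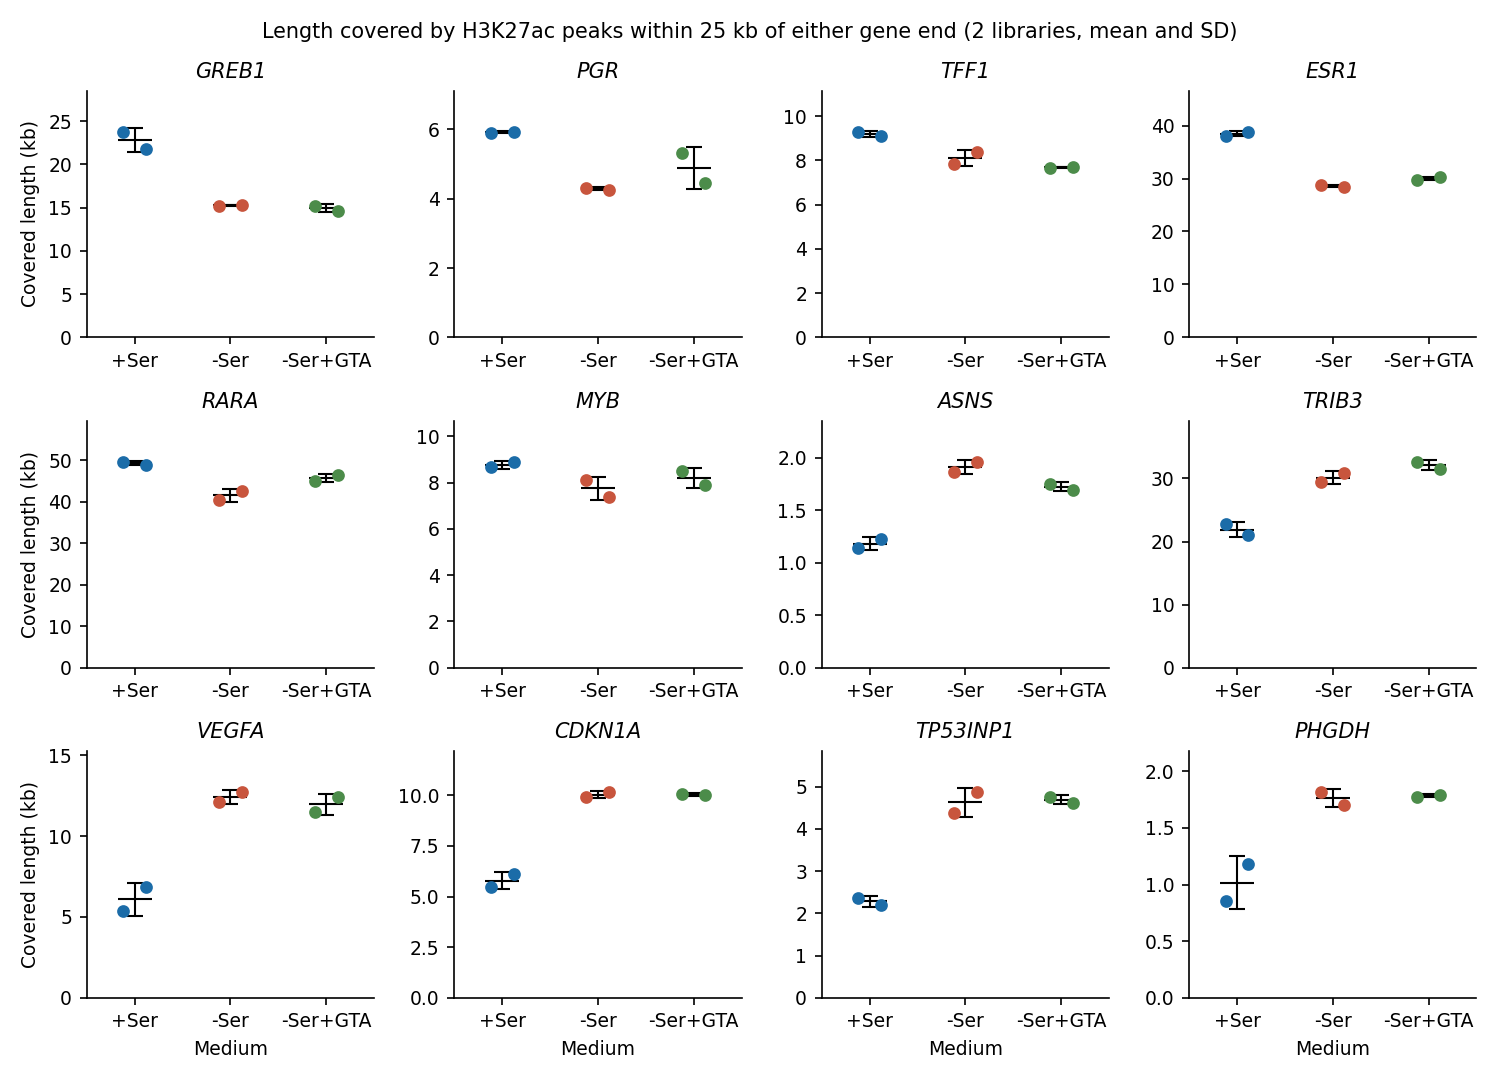
Length covered by H3K27ac peaks (kb) within 25 kb of either end of 12 genes; points are libraries, bars are the mean and SD of 2 libraries per medium. GREB1 fell from 22.8 to 15.3 kb and CDKN1A rose from 5.79 to 10.0 kb without serine, and with GTA they stood at 14.9 and 10.0 kb.

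The genes that make and spend acetyl-CoA went both ways. Of 37 measured genes of this list 3 rose and 3 fell. ACSS1, the mitochondrial acetyl-CoA synthetase, rose from 5.57 ± 0.553 to 10.6 ± 0.332 kb (log2 0.91, adjusted p = 0.00183) and KAT2B, a histone acetyltransferase, from 3.36 ± 0.0912 to 6.47 ± 0.518 kb (log2 0.90, adjusted p = 0.00259). HDAC7, a histone deacetylase, fell from 16.9 ± 0.875 to 9.60 ± 0.611 kb (log2 -0.80, adjusted p = 0.00465) and CRAT, the carnitine acetyltransferase, from 6.75 ± 0.000707 to 4.44 ± 0.269 kb (log2 -0.58, adjusted p = 0.00922). ACSS2, the acetyl-CoA synthetase of cytosol and nucleus, stood at 1.299 ± 0.0495 and 1.00 ± 0.209 kb (log2 -0.33, adjusted p = 0.254), and ACLY at 5.63 ± 0.128 and 5.94 ± 0.205 kb (log2 0.07, and -0.01 with libraries centred on their medians). In camera the list did not pass (adjusted p = 0.827).

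The remaining lists did not pass camera either. Of 29 cell cycle genes 4 fell, with MCM2 (log2 -0.51), MCM7 (-0.24), CCNE1 (-0.54) and E2F2 (-0.38) at adjusted p of 0.0279 to 0.0469, and 1 rose (camera adjusted p = 0.725). Of 23 sterol and lipid genes 3 fell, MVD (log2 -0.65), FASN (-0.21) and SREBF1 (-0.27), and IDI1 rose (log2 0.38; camera adjusted p = 0.827). Of 18 oxidative stress genes 3 rose, FTH1, a ferritin gene (log2 0.70), SLC7A11, the cystine transporter (1.03), and NQO1 (0.30), and OSGIN1 fell (log2 -0.50, but 0.12 at the stricter peak threshold; camera adjusted p = 0.725). Of 20 housekeeping genes 3 rose, UBC (log2 0.45) and B2M (0.57) among them, and 3 fell, RPL13A (-0.55) and TUBB (-0.31) among them (camera adjusted p = 0.725). Of 10 measured markers of basal and mesenchymal cells none passed (camera adjusted p = 0.904), with FN1 at 1.53 ± 0.470 and 0.589 ± 0.322 kb, TP63 at 1.03 ± 0.420 and 1.54 ± 0.279 kb, CD44 at 0.298 ± 0.421 and 0.633 ± 0.438 kb and KRT17 at 0.530 ± 0.144 and 1.23 ± 0.0841 kb. Of 10 measured markers of blood cells CD4 alone passed (log2 0.49, adjusted p = 0.0158; camera adjusted p = 0.827), while CD14 (log2 0.36), CD19 (-0.24) and CD79A (-0.22) did not. With libraries centred on their medians 1 blood cell marker rose and 3 fell, no cell cycle or sterol gene rose while 6 and 5 fell, and of the acetyl-CoA list 2 rose and 4 fell. Median, mean and camera direction differed in sign for the acetyl-CoA (0.04, 0.02, down), basal (0.08, 0.14, down), blood cell (-0.02, 0.05, down), cell cycle (0.03, -0.00, down) and sterol (0.01, 0.03, down) lists. The test fry asks whether a list's genes move on balance one way, without comparing them with other genes. It called the estrogen receptor and luminal lists lower and the amino acid and p53 lists higher (adjusted p = 0.00853 each) and the serine list higher (adjusted p = 0.0166), and in its mixed form, change in either direction, it called every list but the basal one (0.489).

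**Figure D5:**
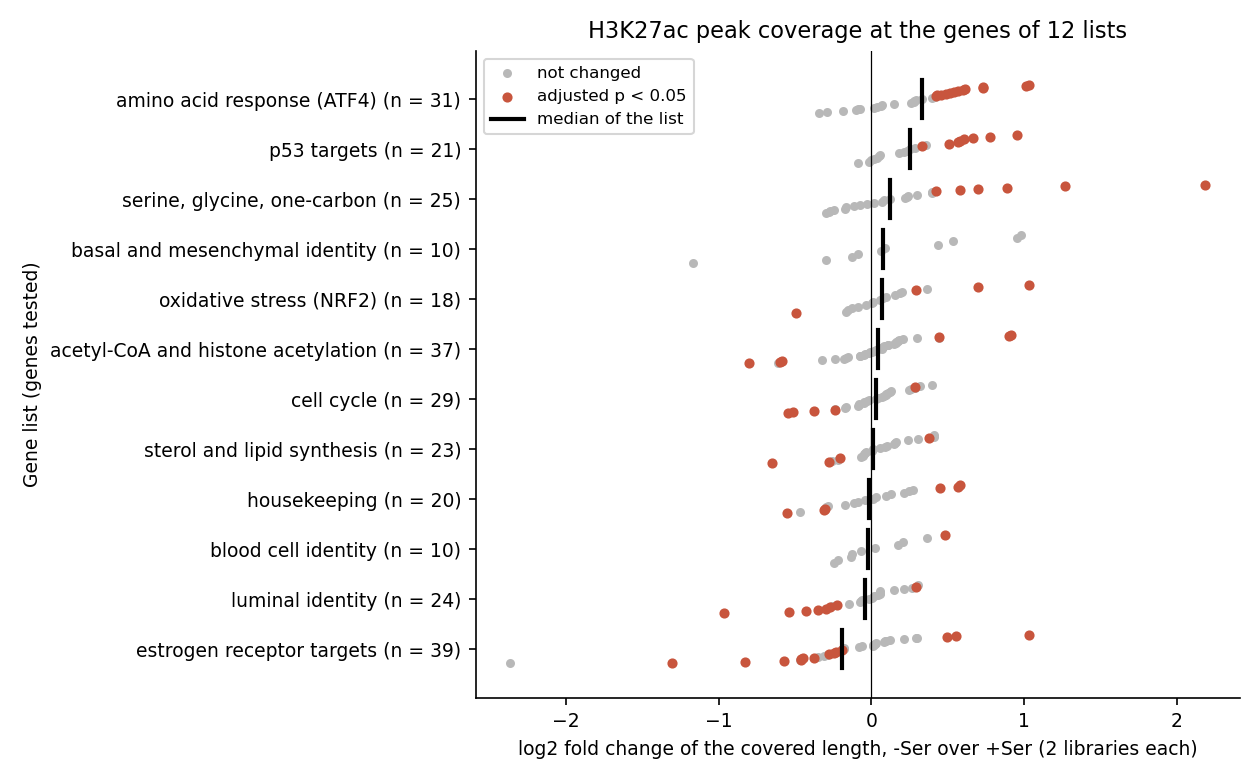
log2 fold change of the covered length without serine against with serine (2 libraries each) at each measured gene of 12 lists; red points passed the limma test and black lines are list medians. Medians run from -0.19 for estrogen receptor targets to 0.33 for the amino acid response.

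Across the genome the largest gains without serine on the log2 scale, with 200 bp added to each length, came at genes with no peak in either serine-fed library. SLC12A1, a salt transporter of the kidney (0 against 2.86 and 3.74 kb in the libraries, adjusted p = 0.00076), HORMAD2 (3.18 ± 0.198 kb), SORL1, a sorting receptor (2.58 ± 0.635 kb), KLF18 (2.20 ± 0.0566 kb), TCIM (2.06 ± 0.538 kb), LOC124904103 (1.98 ± 0.0233 kb), ANKRD55 (1.98 ± 0.151 kb), OR6J1 (1.94 ± 0.306 kb) and CDC42SE2 (1.90 ± 0.397 kb) were listed at 0 with serine, and BAALC at 0.205 ± 0.290 kb against 4.32 ± 0.221 kb. Among the 10 largest losses on this scale were ANPEP, an aminopeptidase gene (5.99 ± 0.445 to 0.295 ± 0.418 kb, adjusted p = 0.00548), GPER1, a G protein-coupled receptor that binds estrogen (5.64 ± 0.340 to 0.859 ± 1.21 kb, adjusted p = 0.0427), and AOX1, an aldehyde oxidase (2.84 ± 0.421 to 0.184 ± 0.260 kb, adjusted p = 0.0128). MRGPRD (2.83 ± 0.499 kb with serine), FGD3 (1.93 ± 0.960 kb), MYOG (1.84 ± 0.485 kb), MGP, matrix Gla protein (1.74 ± 0.134 kb), ADAM2 (1.63 ± 0.332 kb) and CYP4F11 with its neighbour OR10H4 (1.59 ± 0.159 kb for either) were others of the 10 and were listed at 0 in both serine-free libraries without GTA. In kb, ESR1 and GFRA1 lost more than any of these.

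In all, 2725 of 14983 genes changed without serine in limma, 1532 higher at 986 separate loci and 1193 lower at 549. The libraries of the media compared did not overlap at any of the 2725 genes, and at 63.7% of all tested genes, where chance gives 33.3%. With libraries centred on their medians the split was 1175 higher and 2051 lower, since the median log2 change of all genes was 0.06 before and -0.03 after. The count was 1647 with 10 kb windows, and it fell to 1328 and 1620 without serine-fed replicate 1 or 2 and to 708 and 1034 without serine-free replicate 1 or 2. Of 66 named calls these 4 settings ended 16 to 24.

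Adding GTA to serine-free medium took 1 gene past the threshold. BCOR, a transcriptional corepressor gene, rose from 1.91 ± 0.169 to 4.99 ± 0.204 kb (log2 1.299, adjusted p = 0.0467) and was the sole gene of 14983 to pass. In limma 2183 genes had an unadjusted p under 0.05, where chance gives 749. The median gene stood 0.09 higher with GTA on the log2 scale. With libraries centred on their medians 1493 genes had such a p, and 1425 with the adjustment for gene density. The libraries of these media, before centring, did not overlap at 48.1% of tested genes, where chance gives 33.3%. Without each library in turn limma called 0 genes, and the BCOR call ended in 15 of 19 alternatives. Regions did differ: 1036 were gained with GTA over serine-free medium and 597 lost, against 305 to 620 in mixed splits, so the losses lay inside that range. The GTA libraries also held more peaks (mean 32879 against 31768.5). With the same number of strongest peaks per library 888 regions were gained and 720 lost, and at the stricter peak threshold 663 and 499. Mixed splits were not counted at these settings. Left-out libraries changed these counts by construction, to 1686 and 2010 gained without serine-free replicate 1 or 2 and 4108 and 3374 without GTA replicate 1 or 2, and to 2584, 2306, 1109 and 1344 lost in the same order.

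None of the genes named above as lower without serine passed the test with GTA, though some moved far. CYP4F11, with its neighbour OR10H4, stood at 0.969 kb with GTA against 0 without it and 1.59 kb with serine (adjusted p = 0.151), FGD3 at 0.530 kb and MGP at 0.559 kb against 0, and ANPEP (log2 1.90) and AOX1 (1.71) were also higher in mean. FASN and SREBF1 stood near their serine-fed length (log2 -0.02 and 0.08 against serine-fed cells). GREB1 stood at 14.9 ± 0.462 kb with GTA against 15.3 ± 0.0346 kb without it (log2 -0.03, adjusted p = 0.856), ESR1 at 29.98 ± 0.3302 against 28.6 ± 0.225 kb (log2 0.07, adjusted p = 0.458) and PGR at 4.89 ± 0.598 against 4.29 ± 0.0445 kb (log2 0.17, adjusted p = 0.479). SLC39A6 stood at 27.9 ± 1.25 against 24.3 ± 0.193 kb (log2 0.20, adjusted p = 0.172) and RARA at 45.7 ± 1.04 against 41.5 ± 1.47 kb (log2 0.14, adjusted p = 0.191). CDKN1A (log2 0.00), VEGFA (-0.05) and PHGDH (0.02) also did not pass. No member of the 12 lists passed over all genes, and adjusted over the list alone 2 acetyl-CoA genes, 2 p53 targets and 1 gene each of the blood cell, serine and sterol lists rose and 1 basal gene fell. No list passed camera, the lowest adjusted p being 0.131 for the acetyl-CoA, luminal and blood cell lists, all 3 higher. The other lists gave 0.591 for basal, 0.750 for the amino acid, housekeeping, p53, serine and sterol lists, 0.756 for oxidative stress and 0.851 for the cell cycle and estrogen receptor lists. List medians were above 0 for all 12, but with libraries centred on their medians those of the estrogen receptor, housekeeping, luminal, p53 and sterol lists fell below 0. The direction in camera was down, without a call, for the amino acid, basal, cell cycle, housekeeping and sterol lists, and the basal mean was -0.14. By fry the acetyl-CoA (adjusted p = 0.0362) and luminal lists (0.0198) were higher on balance, where the median gene of the genome stood at 0.09. In data simulated for serine removal, with 200 changed genes and as many libraries, limma found 43.0% of changes of 0.5 on the log2 scale and 90.7% of changes of 1, so a p that misses the threshold does not show that the media were alike.

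Cells with GTA also stood apart from serine-fed cells. The p53 targets were higher (10 of 21 rose, 15 adjusted over the list alone, camera adjusted p = 0.000107; adjusted p = 0.270 with an estimated correlation), with CDKN1A at 10.0 ± 0.0643 kb against 5.79 ± 0.436 kb with serine (log2 0.78, adjusted p = 0.00316). Of the amino acid response 14 of 31 rose (15 adjusted over the list alone, camera adjusted p = 0.00155; adjusted p = 0.272 with an estimated correlation), TRIB3 at log2 0.55 and VEGFA at 0.96. Of 39 estrogen receptor targets 5 rose and 5 fell (7 and 8 adjusted over the list alone), and the list was lower than other genes in camera (adjusted p = 0.000206; adjusted p = 0.199 with an estimated correlation), with GREB1 (log2 -0.60, adjusted p = 0.00313), ELOVL2 (-1.96, adjusted p = 0.00198) and SLC39A6 (-0.26, adjusted p = 0.0128) down. After centring on library medians 8 genes of the p53 list and 8 of the amino acid list rose, the latter with a median of 0.15 against 0.32. The serine list rose at 8 of 25 genes (10 adjusted over the list alone; camera adjusted p = 0.0753), with SHMT2 at log2 1.19. In centred libraries 5 of its genes rose and none fell, with a median of 0.08 against 0.26. Of the luminal list 5 fell and 2 rose (5 and 5 adjusted over the list alone; camera adjusted p = 0.0752, downward, with a median of 0.04 and a mean of 0.01), ESR1 at log2 -0.36 and SPDEF at -0.80. In centred libraries 8 luminal genes fell and none rose, with a median of -0.13 and a camera call (adjusted p = 0.00199; range 0.00138 to 0.231).

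Other lists were mixed against serine-fed cells. Of the acetyl-CoA list 6 rose, ACSS1 (log2 1.15) and KAT2B (0.92) among them, and 1 fell (camera adjusted p = 0.411). Of the oxidative stress list 4 rose and none fell (0.361), of the blood cell list 2 rose (0.282), of the cell cycle list 2 rose (0.375), of the housekeeping list 2 rose and 1 fell (0.361), of the sterol list 2 rose and 1 fell (0.512), and of the basal list none changed (0.361). The basal, cell cycle, housekeeping and sterol lists had medians above 0, while their direction in camera was down without a call. With libraries centred on their medians the calls shifted down: 5 cell cycle and 3 sterol genes fell and none rose, 3 acetyl-CoA genes rose and 3 fell, and 2 housekeeping genes rose and 3 fell. The largest gains on the log2 scale included genes named above for serine removal, HORMAD2 at 3.38 ± 2.08 kb, SLC12A1 at 2.52 ± 0.875 kb, SORL1 at 2.32 ± 0.483 kb, KLF18 at 2.28 ± 0.243 kb and BAALC at 4.13 ± 0.0672 kb, with EOMES (1.61 ± 0.0332 kb), ERC2 (1.62 ± 0.310 kb), MATN4 (1.58 ± 0.0099 kb), CPLX2 (1.57 ± 0.272 kb) and LOC124904103 (1.77 ± 0.151 kb). All but BAALC were listed at 0 in both serine-fed libraries. Losses were led by DUSP2, a phosphatase gene (6.99 ± 0.628 to 0.644 ± 0.911 kb, adjusted p = 0.0194). PLEKHG4B and 3 uncharacterised genes that share its window (LOC124900629, LOC124905413, LOC112268347), MYOG, LOC107985876, ADAM2 and SLC5A11 were listed at 0 with GTA, and MRGPRD at 0.205 ± 0.290 kb.

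In limma 2744 genes changed between GTA and serine-fed cells, 2225 higher and 519 lower, and 2211 regions were gained and 2027 lost. The direction depended on scaling: the median gene stood at 0.14, and with libraries centred on their medians 961 genes were higher and 1442 lower, with 2 estrogen receptor targets up and 16 down. The count was 1576 with 10 kb windows, 1500 and 1425 without serine-fed replicate 1 or 2, and 947 and 1164 without GTA replicate 1 or 2.

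The changes without serine and with GTA against the serine-fed libraries overlapped widely: 1291 genes were higher in both, 438 lower in both and none opposite, where independent lists would share 227.5 and 41.3. Both comparisons use the same serine-fed libraries, and libraries simulated without any difference gave a correlation across genes of 0.499 for that reason alone, against 0.852 observed. The covariance was 0.171, which is 0.157 above the simulated one. The 2 serine-fed libraries cannot be divided between the comparisons and still leave replicates, so part of the excess may come from them. The serine and GTA changes, which share the serine-free libraries, correlated at -0.408 against -0.501 in simulations, with a covariance of -0.0469, below the simulated one by -0.0323.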

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

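The whole gene span, centring within each chromosome, the adjustment for gene density, the GTA return under other settings and the bin count at the stricter threshold were chosen after the results were seen. Of 1238 comparisons of called genes named for serine removal, 1084 kept direction and call, 153 kept direction alone and 1 turned. For GTA against serine-fed cells 333 of 362 kept both and 29 kept direction alone. Counts stayed within a factor of 1.5, or shares and similar values within their interval or spread, in 139 cases, while 54 moved further and 1 turned, and lists kept direction and call in 640 cases, became stronger in 10, weaker in 4 and turned in 30. The depth is unknown, so it cannot be said which weak regions a deeper library would have marked.

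With -log10 q of at least 5 the lost regions numbered 1360, those gained with GTA 663, those absent from the serine-free libraries without GTA alone 225, and the share present with GTA was 16.5%. This setting holds fewer peaks by construction. It also turned the difference in peak number to 269 and OSGIN1 to 0.12. With 50% of a region covered the share was 12.1%. With 10 kb windows 1647 genes changed without serine and 1576 with GTA against serine. GTA against serine-free medium had 0 genes in limma at the stricter threshold, with equal peak numbers, a pseudocount of 50 bp, no filter, 10 kb and 50 kb windows, the replicate block, robust moderation and the whole gene span (1746 to 2755 at an unadjusted p under 0.05). The replicate block is no sound pairing, since replicate numbers correlated at -0.0148, -0.0467 and 0.119 across media; it gave 2461 genes without serine and 2352 with GTA against serine. With no filter 1 list, the blood cell one, passed camera for GTA against serine-free medium, and with centred libraries 5 lists, the luminal one among them, passed against serine-fed cells. Except where fewer peaks or samples explain it, the cause was not tested.

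Lists without a call turned direction as follows, with adjusted p. For serine removal the acetyl-CoA list turned with 10 kb windows (0.796), 50 kb windows (0.459), centring within chromosomes (0.882) and the density adjustment (0.946). The basal list turned with centred libraries (0.820), 50 kb windows (0.816), the whole span (0.698) and centring within chromosomes (0.882), and the blood cell list with the last (0.882) and the density adjustment (0.742). For GTA against serine-free medium, 50 kb windows turned the amino acid, cell cycle and estrogen receptor lists (0.872 each) and the housekeeping list (0.791). The stricter threshold turned the cell cycle and p53 lists (0.952 each), equal peak numbers the cell cycle list (0.813), and 10 kb windows the basal and sterol lists (0.986 each). Centred libraries turned the estrogen receptor (0.870) and luminal lists (0.951), and the estrogen receptor list also turned with centring within chromosomes (0.820) and the density adjustment (0.964). Of genes without a call, ACLY turned to -0.0132 with centred libraries, CD19 to 0.0528 with 10 kb windows and KRT17 to -0.28 with 50 kb windows. FOXA1 turned to -0.0099 at the stricter threshold, -0.0824 centred, -0.0112 with 10 kb and -0.0675 with 50 kb windows, -0.11 centred within chromosomes and -0.16 with the density adjustment.

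Leaving out each library in turn gave 2470 to 7268 regions lost and 2140 to 4486 gained without serine, 1066 to 4108 gained and 608 to 2584 lost with GTA, 461 to 793 absent from the serine-free libraries without GTA alone, and a share of 6.77% to 26.6%. It gave 708 to 2532 genes without serine, 0 in each case for GTA against serine-free medium and 947 to 1956 for GTA against serine. A lone library is assumed to vary like the other groups. The adjusted p of the basal list ranged from 0.613 to 0.940 and of the sterol list from 0.671 to 0.886 for serine removal, and for GTA against serine-free medium from 0.335 to 0.994 for housekeeping genes and 0.556 to 0.891 for sterol genes. CD44 ranged from -0.042 to 1.95 and FOXA1 from -0.0128 to 0.0224.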

Other observations

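The tests of a batch, of library enrichment, of gene density, of the PREX1 bin and of both readings of the GTA difference were chosen only after the results were seen. Lost and gained regions were spread unevenly over the chromosomes. Chromosomes 19 and 20 lost 155 and 131 regions and gained 48 each, ratios of 3.23 and 2.73, while chromosome 6 lost 109 and gained 171 (0.637). Chromosome 6 carries the strong gained regions near PREP and VEGFA, and chromosome 20 the PREX1 locus.

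GTA libraries lay closer to the serine-fed ones at genes that had fallen without serine than at genes that had risen. At 1113 of 1193 lower genes (93.3%) the GTA mean lay on the serine-fed side of the serine-free mean, with a median GTA change of 0.22 on the log2 scale, and at 717 of 1532 higher genes (46.8%), with a median of 0.01. With libraries centred on their medians the shares were 81.1% and 71.4% and the medians 0.14 and -0.07. Genes picked for a change in the serine-free libraries lean back towards the others by chance alone, so these shares are no test. Regions gained with GTA over serine-free medium lay near a gene end more often, 157 of 1034 (15.2%, 13.0 to 17.5), than regions lost with it, 33 of 596 (5.54%, 3.84 to 7.69). This difference was not tested, and the number of regions lost with GTA lay within the range of mixed splits.

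Genes changed without serine, with estrogen receptor targets lower and amino acid response and p53 targets higher. More weak peaks in the serine-fed libraries are argued against as the whole cause, since 2710 genes changed with the same number of strongest peaks per library, 2498 of them shared with the 2725. A library bias along gene-rich and gene-poor parts is argued against in the same way (2587 genes after the adjustment for gene density, 2108 shared; estrogen receptor list in camera adjusted p = 0.000186, unadjusted 1.55e-05, though before the adjustment adjusted p = 0.256 with an estimated correlation), and so is the high covered length of the list genes (median at percentile 0.01 of matched random lists). A lower enrichment of the serine-fed libraries (median -log10 q of at most 12.3, against at least 15.6 in every serine-free library) cannot be told apart from the medium for the genes that were higher without serine. Of the genes that were lower, 775 were called at the stricter threshold, against 1193 over all peaks. This does not decide the matter, since the serine-fed libraries held more and narrower peaks over about the same length. A library, sequencing or input batch (the labels give no batch and 1 input per medium) could account for any of these changes, and a response of the cells to serine removal stays open beside it as a hypothesis.

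Clusters of lost regions at single loci without serine. An even scatter of the lost regions over all regions of the serine-fed libraries is argued against, since 0 of 1000 shuffles reached the highest bin of 18. The shuffles took no account of peak strength. Lost regions were weak (median percentile 25.8, against 69.1 for kept regions in the serine-fed libraries), so the shuffles cannot exclude chance clustering of weak peaks. A background or copy number difference over the whole locus may account for the GFRA1 bin, where 6 regions were lost at the stricter threshold, 3 of the 18 among them, and the 9 kept regions also shrank, from a mean of 30.1 to 17.2 kb. Kept regions covered less in both serine-free libraries in 10 of the 12 leading bins, NCAM2 (72.1 to 33.8 kb) among them, and more at PREX1 alone (19.95 to 22.6 kb), a bin picked after its values were seen. At PREX1 lost regions had stood at a median percentile of 38.1. Kept ones moved by -2.45 points (-11.4 to 6.54), like the median of 1514 other bins (-2.27). This interval is nearly as wide as the spread of the other bins (-11.6 to 7.97), so it cannot decide whether the whole locus changed. The growth in kept length at PREX1 was ordinary too, since 458 of the 1514 other bins (30.3%) reached it. A locus-wide difference and the loss of single enhancers both stay open at PREX1 as hypotheses, beside a batch.

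Few genes pass the test between serine-free media with and without GTA. A partial return of the serine change is 1 candidate explanation: GTA returned 16.4% of it (12.8 to 20.04 by a jackknife over chromosomes, which leaves out the spread between libraries; 12.7% and 20.2% with 1 GTA library each). A difference held by the serine-free libraries without GTA alone and unrelated to serine is another, since with the roles of the serine-free groups swapped the share was -3.32% (-7.10 to 0.463; -5.56% and -1.08% with 1 serine-free library each, the former with an interval below 0), where an equal return at every gene would give -19.7%. Both stay open, the first only if GTA also made changes of its own, and a batch per medium cannot be told apart from either.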
